A study of Arabidopsis thaliana with 25 samples.

How the data were processed

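The samples were roots of Arabidopsis seedlings with a PEAR1-GR or a PEAR2-GR transgene, 25 in all in 8 groups of construct and treatment. Total RNA was labelled with biotin by a whole-transcript sense target assay, per the labels' protocols, and hybridised to 1-colour Affymetrix arrays. The values are log2 intensities made by the authors with RMA, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises probes into 1 value per row. Its version, its options and the level of summary are not given in the sources used here. No scanner intensities or detection calls were used, so a low value cannot be called absent.

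The deposited table had 38408 rows and 25 columns, each matched to its sample by name. Rows were named from the platform annotation, and loci and symbols were updated through the gene identifiers of the RefSeq table for assembly TAIR10.1. In that annotation 16746 rows name 1 gene, 758 name several and 20904 name none. Of the rows with 1 gene, 16601 matched the RefSeq table and 145 kept the annotation's name. The named rows cover 59.6% of 27550 protein-coding loci, but 16.8% of loci with a gene symbol and 85.8% of loci without one, so well-studied genes are under-represented. Rows with no gene are unnamed here, not without a gene. Rows with several genes were counted but not named. The array's genome build is not given in the sources used here, so no coordinates are printed, and positions served only to find neighbouring genes.

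Groups, replicate numbers, batch and time came from the labels. A limma model with 1 mean per group was fitted to all 25 arrays, so that the groups share an estimate of the spread, with moderated tests (lmFit and eBayes, limma 3.58.1 in R 4.3.3). Calls are rows with a Benjamini-Hochberg adjusted p under 0.05 over the 17504 rows that name a gene. Rows without a gene were left out because their changes cannot be described, and were tested as an alternative. The comparisons were DEX against DMSO and DEX+CHX against DMSO+CHX in each line, the difference between lines of each, CHX with and without DEX as the mean of both lines, and the lines in DMSO. The rows called the same way in all 4 DEX comparisons were counted as a further result.

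Genes were named by a rule fixed before the data were examined. It takes PEAR1 and PEAR2. From each of the 4 DEX comparisons it takes the 8 largest rises and 5 largest falls among rows with 1 gene past the threshold whose groups do not overlap, which chance gives for 10% of rows with 3 arrays against 3. It takes 6 rises and 6 falls for CHX with DEX, 3 and 3 between lines, 12 and 5 of the shared set, and every member of 21 gene lists. Where a gene had several rows, the row with the highest mean stood for it in lists. The lists held 273 genes, of which 30 had a named row, and 3 lists had at least 3 named members and were tested.

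Lists were tested with limma's camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 3 lists. In addition 57 families of at least 5 genes that share a symbol stem were tested in the same way; this rule was chosen after the files were seen. Expected overlaps are those of independent lists with the same numbers of calls. All comparisons share each row's estimate of the spread, so a row with a small spread passes more readily in several of them. The expected overlaps ignore that and may be too low. For the rows shared by all 4 DEX comparisons, the lists crossed are those that the lines share without and with CHX, a choice made after the count was seen.

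Alternatives listed before the data were examined were a fit on only the groups compared, an intensity trend with a robust prior, leaving out the 33.3% of rows with the lowest mean, quantile normalization once more, a shift of each array to the same 75th percentile, array weights, the replicate number within each line as a block, and leaving out each array in turn. For DEX+CHX, DMSO of the same batch also served as the control. Testing all rows, and leaving out the 3 arrays nearest to the CHX arrays, were added after the data were seen. Batch could not be fitted as a term, because DMSO+CHX was the only treatment in batch A461.

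The scripts were tested on simulated data with known changes in 200 of 17504 rows. For DEX against DMSO in the PEAR1 line, 20.9% of simulated changes of 0.5 (log2) were called, 76.1% of changes of 1 and 100% of changes of 2, with 5 false calls. For the PEAR2 line these were 28.4%, 74.6% and 100%, with 12 false calls. With DEX+CHX the shares were 28.4%, 79.1% and 98.5% in the PEAR1 line and 28.4%, 82.1% and 98.5% in the PEAR2 line. Of 200 simulated lists with no shift, 1.5% had a camera p under 0.05. The simulated noise was independent between rows and had the same spread in every group. These rates therefore test neither the preset correlation nor the shared spread. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.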

Results

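Roots of Arabidopsis thaliana seedlings (ecotype Col-0, 4 days old) were profiled on 25 whole-transcript arrays. The plants carried pRPS5A::PEAR1-GR or pRPS5A::PEAR2-GR, and no line without a GR fusion was included. PEAR1 (AT2G37590) and PEAR2 (AT5G02460) are DOF-type transcription factors, here fused to the hormone-binding part of the glucocorticoid receptor (GR) and driven by a promoter active in dividing cells. Dexamethasone (DEX), a synthetic glucocorticoid, lets such a fusion enter the nucleus. Cycloheximide (CHX), an inhibitor of translation, was added in some samples so that transcripts could respond without newly made protein. Each line was treated with the solvent DMSO for 1 h, or for 2 h with DEX, with DMSO+CHX or with DEX+CHX. Every group held 3 arrays, except DEX+CHX in the PEAR1 line with 4. The labels name 2 arraying batches: DMSO+CHX alone was run in batch A461 and all other groups in batch A451. The labels call the harvested tissue root in one field and root tips in another.

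Replicate arrays were alike, with Pearson correlations across the named rows between 0.988 and 0.994 within a group. An array with CHX and an array without it correlated at 0.890 to 0.922. The first principal component held 80.5% of the variance and separated the CHX arrays from the others. The number of arrays limits the precision. The model takes the spread of a row as equal in all groups, although replicates were slightly more alike with CHX than without it. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Changes are given as log2 values with the standard error (SE) of a limma model, and adjusted p-values are Benjamini-Hochberg values over the 17504 rows that name a gene. Group means of 2.30 or lower are read here as near the floor of the arrays, a limit chosen after the values were seen. A change from or to such a mean is a lower bound, and a difference between 2 such changes has no settled size.

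The row of PEAR2 followed the labels in every sample. It stood at 10.74 ± 0.01 (SD, n = 3) in the PEAR2 line and 6.47 ± 0.15 (n = 3) in the PEAR1 line in DMSO, a difference of -4.27 ± 0.12 (SE, limma adjusted p = 1.26e-16). The lowest of the 12 values in the PEAR2 line was 10.73, and the highest of the 13 in the PEAR1 line was 8.90. DEX moved the row by 0.22 ± 0.12 in the PEAR2 line and by -0.34 ± 0.12 in the PEAR1 line, neither past the threshold. With CHX in the presence of DEX it went from 6.12 ± 0.21 (SD, n = 3) to 8.78 ± 0.10 (n = 4) in the PEAR1 line and from 10.95 ± 0.11 to 12.09 ± 0.03 (n = 3 each) in the PEAR2 line, a mean rise of 1.90 ± 0.08. No row is named PEAR1 in the annotation used, so its level was not analysed here. Of the 273 genes in the lists fixed before the data were examined, 30 had a named row.

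DEX against DMSO in the PEAR1 line asked which transcripts change when PEAR1-GR is activated. The largest rise was in BGLU28, a beta-glucosidase gene, from 3.12 ± 0.63 (SD, n = 3) to 6.61 ± 0.19 (n = 3), a change of 3.49 ± 0.29 or 11.3-fold. AT4G21870, a small heat shock protein gene, rose by 2.73 ± 0.20, and AT5G51440, another small heat shock protein gene, by 1.84 ± 0.27. The receptor-like kinase gene AT1G05700 rose by 2.50 ± 0.27 and AT1G80380, which encodes glycerate kinase of photorespiration, by 2.16 ± 0.21. AT5G28960, AT3G15630 and AT3G15450 rose by 2.01 to 2.17. Among the falls, WAG2, a protein kinase of auxin transport, fell by 2.13 and AT1G22810, an AP2/ERF transcription factor gene, fell by 2.04. AT1G78230 fell by 2.24, AT2G43890 by 2.14 and AT3G50610 by 1.99.

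In all, 222 named rows rose and 316 fell in this comparison, 54 and 77 of them by at least 1 on the log2 scale. Of 8 named auxin genes, 2 fell: GH3.1, which encodes an auxin-conjugating enzyme, fell by 0.53 (SE 0.12, adjusted p = 0.0149), and LBD16, a lateral root regulator, fell by 0.91 (SE 0.18, adjusted p = 0.00486). The same 2 passed when adjusted over the list alone. The list fell as a set (median change -0.24, camera adjusted p = 0.0203), with adjusted p = 0.0945 with an estimated correlation. That median lies between IAA30 (-0.25, at 2.14 with DEX) and IAA20 (-0.23, from 1.82 to 1.59). Both stood near the floor with DEX, so the size of the median is not settled. GH3.1 lost its call without PEAR1 DMSO replicate 1, PEAR1 DMSO replicate 2 or PEAR1 DEX replicate 2, and a fit of the 6 arrays alone ended the calls of GH3.1 and LBD16. None of the 5 named phloem genes (OPS, CLE45, CLE25, CLE26, SWEET11) and none of the 3 named cambium genes (MOL1, CLE41, CLE44) passed the threshold over all rows by limma, and 1 cambium gene, CLE41 at -0.52, did when adjusted over the list alone. RCA, the only named marker of green tissue, fell by 0.61 (SE 0.16, adjusted p = 0.0414), a call lost when any 1 of 5 of the 6 arrays was left out. The DMSO arrays were sampled at 1 h and the DEX arrays at 2 h, so time and DEX cannot be told apart. PEAR1 DEX vs DMSO gave 122 calls against 538 when its 6 arrays were fitted alone, and 349 without PEAR1 DEX replicate 1.

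DEX against DMSO in the PEAR2 line asked the same of PEAR2-GR. BGLU28 again had the largest rise, from 2.42 ± 0.29 (SD, n = 3) to 6.99 ± 0.24 (n = 3), a change of 4.58 ± 0.29 or 23.9-fold. AT4G21870 rose by 3.41 ± 0.20, AT3G54780 by 2.84 ± 0.23 and AT1G05700 by 2.69 ± 0.27. AT1G47395, which encodes a small peptide of the iron deficiency response, rose by 2.56 ± 0.31, and the DREB-type transcription factor gene DREB2C by 2.19 ± 0.24. AT5G37990 rose by 2.22 ± 0.40 and AT5G48430 rose 4.30-fold (SE 0.19 on the log2 scale). WAG2 fell by 2.18 and AT1G22810 fell by 2.09. AT1G77200, another AP2/ERF gene, fell by 2.16 and AT2G43890 fell by 2.86. AT4G10860 also fell by at least 2.86, to 1.85 near the floor, but its DMSO arrays were far apart (4.71 ± 2.18, SD, n = 3).

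Here 376 named rows rose and 341 fell, 103 and 75 of them by at least 1. GH3.1 fell by 0.71 (SE 0.12, adjusted p = 0.00103), the only auxin gene past the threshold of 8, and the list did not move as a set (median 0.22, camera adjusted p = 0.857). ZAT10, an early stress response zinc finger gene, rose by 0.85 (SE 0.20, adjusted p = 0.0146), a call lost without PEAR2 DMSO replicate 1, PEAR2 DMSO replicate 3 or PEAR2 DEX replicate 1. The clock gene GI rose by 0.50 (SE 0.09, adjusted p = 0.00194). No named phloem or cambium gene passed over all rows by limma, and the cambium gene CLE44, at 0.62, did when adjusted over the list alone. Time and DEX are again confounded. A fit of the 6 arrays alone ended the calls of GH3.1, ZAT10 and GI and gave 1.7e+02 calls against 717, and the count was 465 without PEAR2 DMSO replicate 3.

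**Figure D1:**
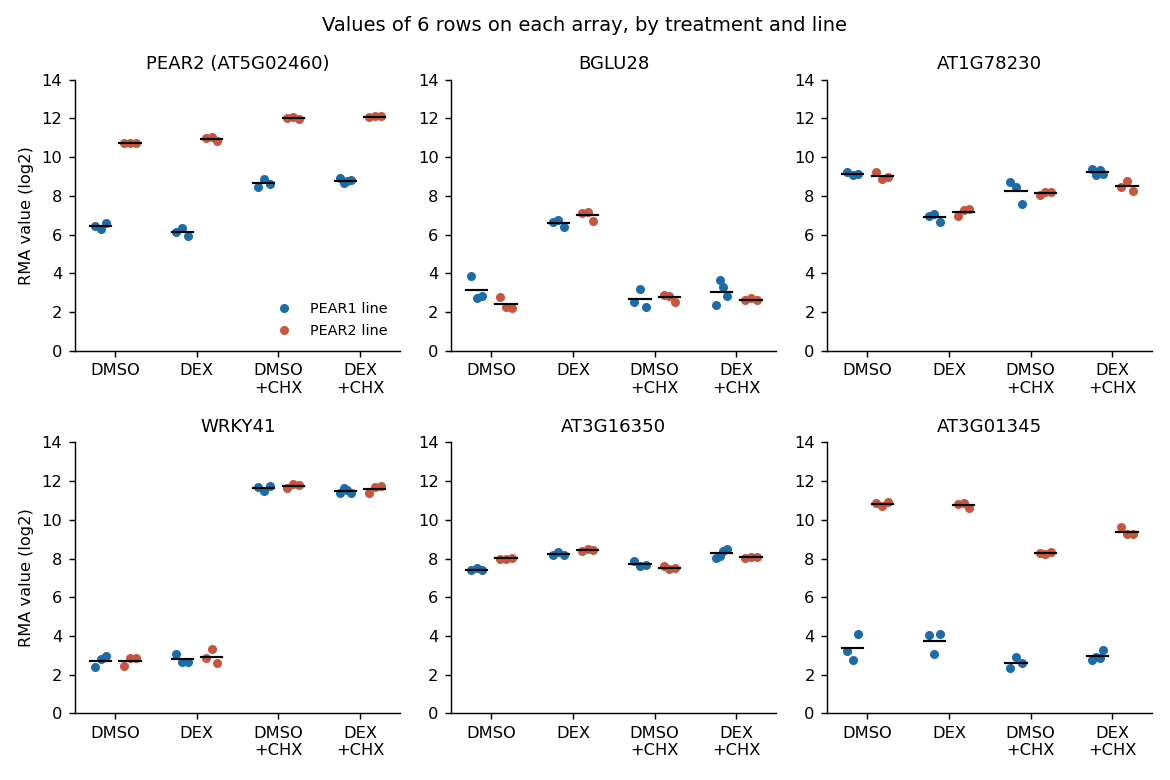
RMA values (log2, vertical axes) of 6 rows on each of the 25 arrays, by treatment (horizontal axes), with the PEAR1 line in blue and the PEAR2 line in red; each point is an array and each bar the group mean. PEAR2 (AT5G02460) was higher in the PEAR2 line throughout, BGLU28 rose with DEX and did not pass the threshold with DEX+CHX, and WRKY41 rose by 8.69 with CHX in the presence of DEX.

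The DEX responses of the lines were compared with each other. Of the calls, 107 rises and 115 falls were common to both lines, where independent lists would share 4.77 and 6.16. These comparisons have no array in common, but they share each row's estimate of the spread. Both set DMSO at 1 h against DEX at 2 h, and no line without a GR fusion was treated. An effect of time or of DEX itself could therefore also be shared and cannot be told apart from the fusions. Only AT1G63740, an immune receptor-type gene, and JAL22, a lectin gene, passed in opposite directions (0.48 and -0.85 for AT1G63740, -0.83 and 0.85 for JAL22, PEAR1 and PEAR2 lines). Both were named after their values were seen. Across all named rows, which are not independent replicates, the changes correlated at 0.31.

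A test of the difference between the responses found 5 rows higher and 14 lower in the PEAR1 line, and over all rows of the table, with or without a gene, 49 higher and 28 lower, so the balance between the directions is not settled. The largest were AT1G51820, a receptor-like kinase gene (-3.04 ± 0.58, adjusted p = 0.0356), AT5G37990 (-2.86 ± 0.56, adjusted p = 0.0479) and AT2G05510, a glycine-rich protein gene (-2.26 ± 0.32, adjusted p = 0.00558). AT2G05510 rose by at least 2.00 in the PEAR2 line, but stood at 1.84 to 2.13 in the other 3 groups, near the floor, as AT1G51820 (2.03) did in DMSO and AT5G57510 (2.23) with DEX in the PEAR2 line, so the sizes of these differences are not settled. The calls of AT1G51820 and AT5G37990 were each lost without any 1 of 9 of the 12 arrays. AT5G57510 (1.66 ± 0.29), AT1G63740 (1.33 ± 0.16) and AT3G06990 (1.33 ± 0.23) were the rises by the rule, and AT1G52342 and AT5G43020, named after their values were seen, complete the 5. The count was not stable: it was 2 with the 12 arrays alone, 56 without PEAR2 DMSO replicate 2, 37 without PEAR2 DEX replicate 1, 35 without PEAR2 DEX replicate 3, 12 without PEAR1 DEX replicate 1, 8 without PEAR2 DEX replicate 2, 7 without PEAR1 DMSO replicate 1 and 5 without PEAR1 DEX replicate 3.

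DEX+CHX against DMSO+CHX asked which transcripts respond to the fusion while translation is blocked. In the PEAR1 line AT1G57850 rose from 2.53 ± 0.26 (SD, n = 3) to 4.65 ± 0.54 (n = 4), a change of 2.12 ± 0.34. AT4G35655 (2.09 ± 0.38), AT1G73120 (2.02 ± 0.38), AT2G28780 (1.91 ± 0.31), AT4G00910 (1.89 ± 0.35), AT3G51642 (1.80 ± 0.34), AT5G54700 (1.78 ± 0.33) and AT5G11070 (1.62 ± 0.22) followed. The immune receptor-type gene AT5G17970 fell by 1.79, AT2G27320 by 1.77 and AT2G03230 by 1.74. CCOAMT, named for caffeoyl-CoA 3-O-methyltransferase, fell by 1.72 and AT4G09120 by at least 1.68. BGLU28, which led the DEX response without CHX, stood at 0.38 ± 0.27 here, not past the threshold. AT5G54700 had fallen with DEX alone (-1.86), and AT1G78230, which also fell there, rose here by 0.96.

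In this comparison 381 named rows rose and 247 fell, 54 in each direction by at least 1. Among the 5 named phloem genes, OPS, a polarity factor of the protophloem, rose by 0.74 (SE 0.21, adjusted p = 0.0482). The phloem list rose as a set (median 0.31, camera adjusted p = 0.0415), with adjusted p = 0.0937 with an estimated correlation, and quantile normalization once more left none of the 5 past the threshold. LBD16 rose by 0.62 (SE 0.17, adjusted p = 0.0441), and no list member fell past the threshold. The auxin list had a median of 0.24 (camera adjusted p = 0.0599) and the cambium list 0.22 (camera adjusted p = 0.0799), with none of its 3 genes past the threshold. The OPS call was also lost without each of PEAR1 DEX+CHX replicates 1, 2, 3 and 4 and of PEAR1 DMSO+CHX replicates 1 and 3, and the LBD16 call without 5 of the 7 arrays and with quantile normalization once more. A fit of the 7 arrays alone ended both calls. Batch and DEX cannot be told apart here, because DMSO+CHX was arrayed in a batch of its own. PEAR1 DEX+CHX vs DMSO+CHX gave 380 calls against 628 when its 7 arrays were fitted alone and 1105 with array weights, and the count was 227 without PEAR1 DMSO+CHX replicate 3, 333 without its replicate 2, 390 without its replicate 1 and 329 without PEAR1 DEX+CHX replicate 3.

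In the PEAR2 line, DEX+CHX raised AT2G07981 by 2.63 ± 0.32 over a mean of 0.54 ± 0.19 (SD, n = 3), close to the floor of the arrays. AT1G26250 rose by at least 1.96 ± 0.40, from 1.34 near the floor, and AT2G01023 by 1.76 ± 0.18. AT1G49200 (1.68 ± 0.31, from 1.93), AT5G05960 (1.49 ± 0.22), the formin gene AT3G05470 (1.44 ± 0.18), AT5G17040 (1.36 ± 0.31, from 2.20) and the receptor-like kinase gene AT2G45340 (1.34 ± 0.16) rose as well. AT2G01023 (1.26) and AT2G45340 (0.91) also rose with DEX alone in this line. Of its named DEX calls, AT3G54780 rose with DEX+CHX too (1.06), whereas AT5G37990 (-1.43) and AT1G77200 (0.70) went the other way. Among the falls, AT2G03230 fell by 3.05, AT2G44070 by 2.91, AT5G55270 by at least 2.74 to 1.37 near the floor, AT2G27320 by 2.63 and AT4G09120 by 2.50. The falling rows AT2G03230, AT2G27320 and AT4G09120 were among the 5 largest falls in both lines. They stood at 2.28 to 4.48 in the DEX+CHX groups and at 1.54 to 2.30 without CHX, near the floor, where a fall with DEX could not have been seen.

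For the PEAR2 line 693 named rows rose and 609 fell, 54 and 159 of them by at least 1. Of the 5 named phloem genes, 2 rose: CLE25, a signalling peptide gene of the phloem, by 1.02 (SE 0.17, adjusted p = 0.000711), and SWEET11, a sucrose exporter gene, by 0.75 (SE 0.23, adjusted p = 0.0483). The phloem list rose as a set (median 0.40, camera adjusted p = 0.00648), and its adjusted p = 0.0283 with an estimated correlation. None of the 8 auxin and 3 cambium genes passed over all rows (camera adjusted p = 0.280 and 0.386), and 1 auxin gene, LBD16 at 0.58, did when adjusted over the list alone. SWEET11 dropped out with either other scaling and without any of 4 arrays (PEAR2 DEX+CHX replicates 1 and 2, PEAR2 DMSO+CHX replicates 1 and 3). GI rose by 0.31 (SE 0.09, adjusted p = 0.0437), a call lost without any 1 of the 6 arrays and with either other scaling. A fit of the 6 arrays alone ended the calls of SWEET11, GI and AT1G26250. Batch and DEX are confounded as in the other line. PEAR2 DEX+CHX vs DMSO+CHX gave 569 calls against 1302 when its 6 arrays were fitted alone, and the count was 696 without PEAR2 DEX+CHX replicate 1, 711 without PEAR2 DMSO+CHX replicate 3 and 817 without PEAR2 DMSO+CHX replicate 1.

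**Figure D2:**
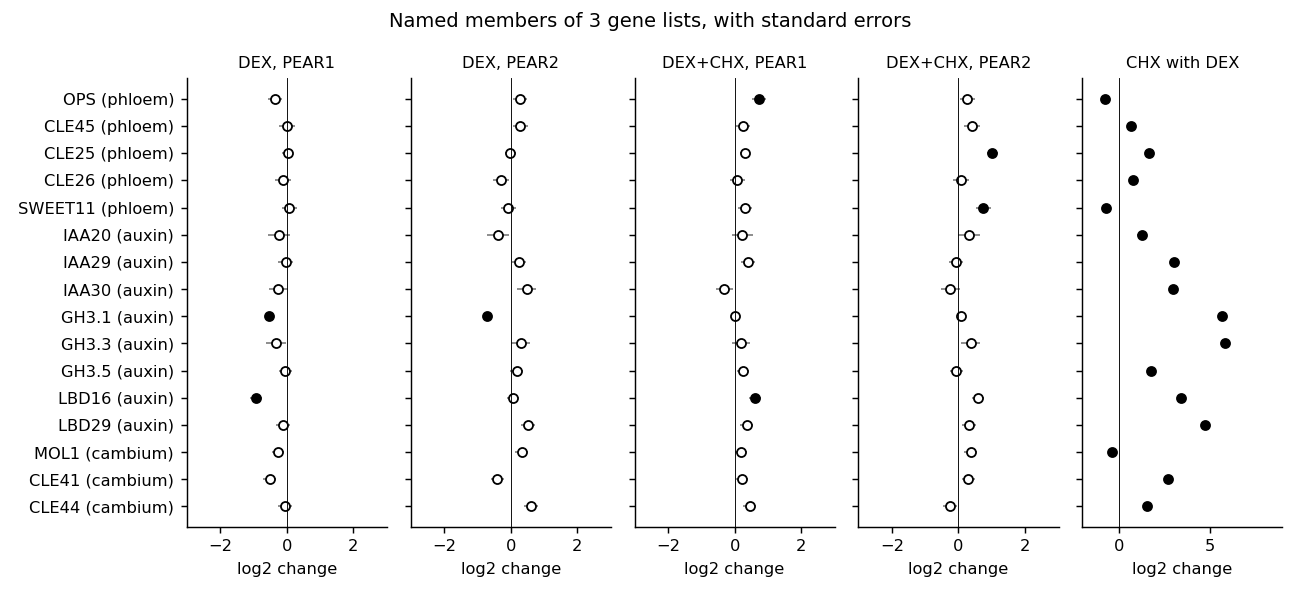
Change (log2, horizontal axes) of the 16 named members of the phloem, auxin and cambium lists in 5 comparisons, with bars of 1 SE; filled points passed the adjusted p threshold of 0.05 and open points did not. CLE25 was the largest rise with DEX+CHX in the PEAR2 line (1.02), and all 8 auxin genes lay to the right of 0 with CHX.

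The calls with CHX were compared between lines and with those without CHX. Between the lines 188 rises and 133 falls were common, where independent lists would share 15.1 and 8.59, and no row passed in opposite directions. The changes correlated at 0.56 across rows. Within the PEAR1 line, 9 rises and 9 falls with DEX passed in the same direction with DEX+CHX, where independent lists would share 4.83 and 4.46, and 64 rows passed in opposite directions, where they would give 10. In the PEAR2 line 38 rises and 21 falls were common (14.9 and 11.9 if independent) and 57 rows were opposite (26.6). Calls in the same and in opposite directions thus both exceeded the numbers for independent lists. The shared spread of each row can give such an excess without a shared response. The changes with and without CHX correlated at -0.09 in the PEAR1 line and -0.02 in the PEAR2 line. Both groups of the DMSO and DEX comparison lay in 1 batch, whereas DEX+CHX and DMSO+CHX did not. DMSO was sampled at 1 h and the other groups at 2 h.

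Only AT3G16350 rose and only UGT72E2 fell in all 4 DEX comparisons. AT3G16350 rose by 0.82 ± 0.11 (PEAR1) and 0.42 ± 0.11 (PEAR2) with DEX, and by 0.55 ± 0.10 and 0.52 ± 0.11 with DEX+CHX. UGT72E2, which encodes a glycosyltransferase of lignin precursors, fell by 0.68 and 0.72 with DEX and by 0.84 and 0.63 with DEX+CHX. Crossing the calls that the lines shared with DEX and those they shared with DEX+CHX as independent lists would give 2.02 rows, so the count of 2 is no more than chance gives. The count of 2 was 0 with only the arrays compared, 8 without the dimmest rows, 5 with the intensity trend, with array weights and with the 75th percentile scaling, and 1 without PEAR2 DMSO replicate 1. It was 4 without PEAR1 DMSO replicate 2, PEAR1 DEX replicate 3, PEAR1 DEX+CHX replicate 4, PEAR1 DMSO+CHX replicate 1 or PEAR2 DMSO+CHX replicate 2.

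**Figure D3:**
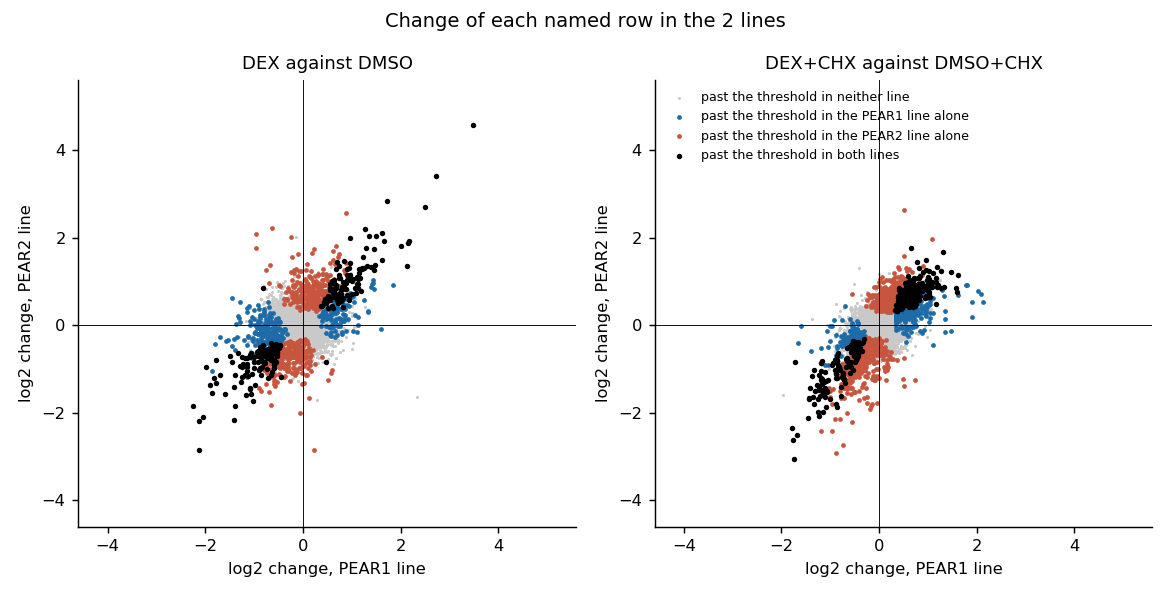
Change (log2) of each of the 17504 named rows in the PEAR1 line (horizontal axes) and the PEAR2 line (vertical axes), with DEX against DMSO on the left and DEX+CHX against DMSO+CHX on the right; colours show where a row passed the threshold. The point farthest to the upper right on the left is BGLU28 (3.49 and 4.58), and no row on the right passed in opposite directions.

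The test of the difference between lines with CHX found 3 rows, all higher in the PEAR1 line: AT5G55270 (2.01 ± 0.32), AT5G28000 (1.99 ± 0.32) and AT5G45095 (1.74 ± 0.28), each with adjusted p = 0.0214 by limma. AT5G55270 stood at 1.40 and 1.37 with DEX+CHX and at 2.13 in PEAR1 DMSO+CHX, near the floor, so the size of its difference is not settled. None was lower. Of the 17504 rows tested, 1079 had an unadjusted p under 0.05 by limma, which chance alone would give for a share of 0.05. A shift between batches that adds the same amount in both lines cancels in this test. The count was 0 without PEAR1 DEX+CHX replicate 2, PEAR1 DEX+CHX replicate 3, PEAR1 DMSO+CHX replicate 2, PEAR1 DMSO+CHX replicate 3 or PEAR2 DMSO+CHX replicate 3. It was 1 without PEAR2 DEX+CHX replicate 1, 6 without PEAR1 DMSO+CHX replicate 1, 8 without PEAR2 DMSO+CHX replicate 2 and 9 without PEAR2 DEX+CHX replicate 2. Over all rows of the table, with or without a gene, it was 0, and after quantile normalization once more it was 1. Of 100 splits of the same arrays, the real one included, 8 gave at least as many, so chance could not be excluded.

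The effect of CHX in the presence of DEX was taken as the mean of both lines, with batch and time held equal. WRKY41, a transcription factor gene of the defence-related WRKY family, rose by 8.69 ± 0.12. AT1G34050 (8.67 ± 0.17), AT1G07135 (8.41 ± 0.19), AT5G57510 (8.26 ± 0.14), AT5G40000 (8.23 ± 0.24) and AT5G11140 (8.15 ± 0.23) rose by similar amounts. All 8 named auxin genes rose, among them GH3.3 (5.83 ± 0.20), GH3.1 (5.68 ± 0.08), LBD29 (4.72 ± 0.14) and IAA29 (3.03 ± 0.15), a repressor of auxin response. The auxin list had a median of 3.23, with camera adjusted p = 2.67e-08 and adjusted p = 0.000343 with an estimated correlation. The stress genes ZAT10 and CML38, a calmodulin-like gene, rose by 6.11 ± 0.14 and 55.6-fold. CLE41 (2.69 ± 0.13) and CLE44 (1.56 ± 0.15), peptide genes of the cambium, also rose, and the cambium list of 3 had camera adjusted p = 0.0944.

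Some falls with CHX were limited by the floor. AT4G03292 fell by 4.53, AT1G78210 by at least 4.30 and AT2G41810 by 4.22. BGLU28 fell by 3.96, AT4G00910 by 3.40 and AT1G47395 by at least 11.3-fold. With DEX+CHX AT1G47395 stood at 1.57 to 1.58 and AT1G78210 at 1.58 to 1.64, near the floor, so their falls are lower bounds. Of the genes named above for the largest rises with DEX in either line, AT5G37990 (-1.55), AT4G21870 (-1.46), AT5G28960 (-1.36), AT3G15450 (-0.64), AT3G15630 (-0.61) and AT1G80380 (-0.55) were also lower with CHX in the presence of DEX. DREB2C (2.02), AT1G05700 (2.15-fold) and AT3G54780 (0.74) rose, and AT5G51440 and AT5G48430 did not pass. Both comparisons use the same DEX arrays, so part of this opposition is built in. PHV, an HD-ZIP III transcription factor gene of vascular patterning, fell by 0.87 (SE 0.13), LHW, a regulator of vascular cell division, fell by 0.78 (SE 0.09) and AUR1, a mitotic kinase gene, fell by 0.54 (SE 0.10). The phloem genes split, with CLE25, CLE45 and CLE26 up and OPS and SWEET11 down. In total 3964 named rows rose and 5752 fell, 1862 and 1040 of them by at least 1. The split depended on scaling: quantile normalization once more moved the median change of all named rows from -0.12 to 0.13 and gave 6249 rises and 4200 falls, and changes such as those of AUR1 are to be read against that shift.

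Without DEX, CHX gave 4225 rises and 5250 falls in the mean of both lines, or 5954 and 4158 after quantile normalization once more. WRKY41 rose by 8.98 ± 0.12 and BGLU28 stood at -0.07 ± 0.21, not past the threshold. Of the other genes raised by DEX and lower with CHX in its presence, AT4G21870 (1.97), AT1G80380 (1.68), AT3G15630 and AT3G15450 (both 2.14-fold) rose here. AT1G47395 fell by 1.57, and AT5G28960 (-0.29) and AT5G37990 (0.47) did not pass. AT5G28960 stood near the floor in PEAR2 DMSO (1.46), PEAR2 DMSO+CHX (1.25) and PEAR1 DMSO+CHX (2.04), so its lack of a call is not read. Of the calls, 3381 rises and 4280 falls were common to both CHX comparisons and 127 were opposite. This comparison is confounded with batch and with time, since DMSO+CHX was sampled at 2 h in batch A461 and DMSO at 1 h in batch A451. The genes raised by DEX were picked against the same DMSO arrays, so part of a rise of those genes here is built in.

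The lines differed before activation. In DMSO, 15 named rows were higher in the PEAR1 line and 18 lower, and over all rows, with or without a gene, 43 were higher and 20 lower, so the balance is not settled. AT3G01345 showed the largest difference, at 3.36 ± 0.68 (SD, n = 3) in the PEAR1 line and 10.83 ± 0.10 (n = 3) in the PEAR2 line (-7.47 ± 0.26, adjusted p = 1.71e-14). The PEAR2 row (-4.27) and AT4G10860 (-3.03 ± 0.57, adjusted p = 0.0265, at 1.68 in the PEAR1 line near the floor) followed. QQS, a gene that affects starch content, was higher in the PEAR1 line (2.44 ± 0.23), as were AT2G28780 (1.94 ± 0.33) and AT3G45160 (1.32 ± 0.24). The phloem gene SWEET11 was lower in the PEAR1 line (-1.25, adjusted p = 0.0211). Only AT3G01345, PEAR2 and QQS differed past the threshold in the same direction in all 4 treatments, by -7.47 to -5.68, -4.83 to -3.30 and 1.68 to 2.44. The count of 33 was 3 with the 6 arrays alone, 9 without PEAR1 DMSO replicate 1, 12 without PEAR1 DMSO replicate 3, 15 without PEAR2 DMSO replicate 2, 20 without PEAR2 DMSO replicate 3, 21 without PEAR2 DMSO replicate 1 and 59 with the intensity trend and robust prior.

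Remaining list members with a named row were few. ARR15 and ARR16, response regulator genes of cytokinin signalling, changed by -0.21 and -0.22 with DEX in the PEAR1 line. In the PEAR2 line the values were -0.14 and 0.13. None passed the threshold, nor did they in any other comparison here. ARR16 stood at 1.69 to 2.21 in all groups, near the floor, where a fall could not have been seen. ARR15 stood near the floor with DEX (2.22 in the PEAR1 line, 2.17 in the PEAR2 line) and in PEAR1 DEX+CHX (2.16). In its other groups ARR15 stood just above that limit, at 2.31 to 2.45, which left little room for a fall to be seen. BBM, EXPA7 and EXPA18 passed in none of the 4 DEX comparisons. With CHX in the presence of DEX, the root meristem gene BBM rose by 0.79 ± 0.16, and the root hair gene EXPA18 fell by 0.78. HSP22 stood at 1.34 to 1.77 in all 8 groups, near the floor, so neither its fall with CHX nor its lack of calls with DEX is read. IAA20, IAA30 and GH3.5 passed in none of the 4 DEX comparisons. IAA20 stood at 1.59 to 2.02 without CHX, near the floor, where a fall with DEX could not have been seen. IAA30 stood near the floor with DEX in the PEAR1 line (2.14) and in DMSO in the PEAR2 line (1.89). The lists for HD-ZIP III targets, xylem, glucosinolate synthesis, jasmonate, nucleolus, endodermis and root cap had no named row and were not analysed here.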

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

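The tests of the arraying batches, of the DEX calls in the presence of CHX and of the GR fusion acting on AT3G01345 were chosen only after the results they measure were seen, and the deciding rule of the last was changed once its result was known. The changes from DMSO under the second pattern were also computed afterwards, and the readings of the time test, of the background test and of the shared rows were then withdrawn. The others were written down before.

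Among the 4 PEAR1 DEX+CHX arrays, 3 of 61 values tested stood apart from the other 3, where chance gives about 1 in 20. These were AT2G28780 in replicate 1 (7.16, others 6.14 to 6.22), AT2G03230 in replicate 2 (5.05, others 3.54 to 3.75) and AT5G45095 in replicate 1 (3.93, others 4.37 to 4.44).

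The DEX response differed between the lines for 19 rows by the interaction test, with AT5G57510 (1.66), AT1G63740 (1.33), AT3G06990 (1.33), AT1G51820 (-3.04), AT5G37990 (-2.86) and AT2G05510 (-2.26) as the named ones. With CHX the count was 3: AT5G55270 (2.01), AT5G28000 (1.99) and AT5G45095 (1.74). The sizes for AT5G57510, AT1G51820, AT2G05510 and AT5G55270 are not settled, since groups stood near the floor of the arrays. Chance could not be excluded for either count: 8 of 100 splits gave as many as 19, the highest other being 60, and 8 of 100 gave as many as 3, the highest other being 20.

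Rows that name no gene also changed. Of 20904 such rows, 533 passed with DEX in the PEAR1 line (212 up, 321 down), 585 in the PEAR2 line (305 up, 280 down), 582 with DEX+CHX in the PEAR1 line (365 up, 217 down) and 1239 in the PEAR2 line (725 up, 514 down). With CHX 12905 passed in the presence of DEX (2806 up, 10099 down) and 12489 without it (3007 up, 9482 down). The DEX response differed between the lines for 44 higher and 16 lower in the PEAR1 line, 0 did with CHX, and 30 were higher and 7 lower in that line in DMSO. Row 13402027, which is not named here, was higher in the PEAR1 line by 4.63 in DMSO (9.95 against 5.31).

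The first pattern weighed was that the DEX+CHX calls were alike in both lines but unlike the DEX calls. Of the PEAR1 calls 94.9% had the same sign in the PEAR2 line, but only 36.62% of PEAR1 and 44.93% of PEAR2 calls had the same sign in the DEX comparison of their own line, which lay within 1 batch. A batch difference that acts on single genes may account for this and cannot be told apart from DEX acting only while translation is blocked, since DMSO+CHX had a batch of its own. The DEX comparison also set DMSO at 1 h against DEX at 2 h, whereas both groups with CHX were sampled at 2 h. Changes with time may therefore also set the comparisons apart, and this was not tested. For a difference in background, dim and bright rows differed by -0.0051 in the PEAR1 line (-0.0191 to 0.0205 with an array left out), under the bound of 0.05. The PEAR2 line did not meet it at -0.055 (-0.0968 to -0.0044). This test cannot decide, because RMA had already corrected background. DEX against DMSO in the PEAR2 line, within 1 batch, also differed more, at 0.0926 (0.0714 to 0.1097). The DEX calls did not keep their direction with CHX (38.29% in the PEAR1 line and 51.05% in the PEAR2 line).

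The second pattern was the rows that fell with DEX against DMSO. DMSO was sampled at 1 h and DEX at 2 h, so a fading response to handling may lower transcripts with time, and such transcripts would be raised by CHX. The rows that fell in the PEAR1 line had a median CHX change of 0.6161 in the PEAR2 line and those that fell in the PEAR2 line 0.7987 in the PEAR1 line, but this was taken from DEX arrays on which the same rows had also fallen (medians of -0.3695 and -0.4034), which raises it by construction and voids the test. Taken from DMSO instead, the medians were 0.251 and 0.2972 with DEX+CHX and 0.2672 and 0.2882 with DMSO+CHX (another batch), where the central 95% of random lists matched on level ended at -0.0578 at the highest. Genes raised by CHX that were repressed by the fusions would give the same, so time after transfer and repression cannot be told apart.

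The third pattern was the lower level of AT3G01345 in the PEAR1 line. DEX moved it by -0.0489 in the PEAR2 line without CHX and by 1.0944 with CHX, the latter confounded with batch. The intervals together ran from -0.5984 to 1.644, so an effect of DEX on this row could not be excluded. The difference between the lines in DMSO, without DEX, was far larger at -7.47, which argues against activation by DEX as its source. Activity of the fusion without DEX was not tested. Under the deciding rule as first written, the value with CHX alone would have counted in favour of activity of the fusion. The 10 nearest named genes had a median difference of 0.0444 (-0.317 to 0.7638). This argues against a raised level in the PEAR2 line that spreads to neighbours. The levels of these genes were not examined, and a gene near the floor could not show a loss. A loss in the PEAR1 line that spreads to neighbours could therefore not be excluded. A difference in the genetic background of the lines was not tested.

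Other splits of the same arrays were counted for each comparison. The 10 splits of 3 against 3 arrays are too few for a share under 0.05: the real counts and the highest others were 538 and 2 (PEAR1 DEX), 717 and 6 (PEAR2 DEX), 1302 and 0 (PEAR2 DEX+CHX) and 33 and 9 (lines in DMSO), with 1 split as large in each. For PEAR1 DEX+CHX only the real split of 35 gave as many as 628 (highest other 101), a share under 0.05. That split also divides the 2 batches, so the share does not tell DEX from batch. The share was 1 of 100 for CHX with DEX at 9716 (highest other 8531) and for CHX without DEX at 9475 (highest other 6805). CHX without DEX is also split by batch and time. The shares were not adjusted over the comparisons. For the 2 shared rows 1 of 100 splits gave as many (highest other 0), but 0 of the 99 other splits had a call in each of the 4 comparisons and so none could share a row, which says nothing about chance.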

How the results depend on the processing

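The tests on all rows of the table and without the 3 arrays nearest to those with CHX (PEAR1 DMSO replicate 1, PEAR2 DMSO replicate 2 and PEAR2 DEX replicate 3) were chosen after the data were seen. Of 3917 values of named genes under alternatives, 3668 kept their side of the threshold, 173 lost the threshold, 39 gained it and 37 reversed. Direction was compared only where the main or the alternative value passed the threshold. Low signal limits the dimmest rows. Where no reason is given, the cause was not tested.

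With only the groups compared, which leaves fewer arrays to estimate the spread, the counts were 122 (PEAR1 DEX), 1.7e+02 (PEAR2 DEX), 380 (PEAR1 DEX+CHX), 569 (PEAR2 DEX+CHX), 2 (difference between lines), 3 (lines in DMSO) and 0 (shared, by limma). With the intensity trend and robust prior they were 49 (difference between lines), 59 (lines in DMSO) and 5 (shared). Without the dimmest rows, which tests fewer rows, they were 37 (difference between lines), 5 (the same with CHX) and 8 (shared). Quantile normalization once more gave 30 (difference between lines) and 1 (with CHX), and the shift to the same 75th percentile 5 (shared). Array weights, which let the spread differ between arrays, gave 433 (PEAR1 DEX), 548 (PEAR2 DEX), 1105 (PEAR1 DEX+CHX) and 1589 (PEAR2 DEX+CHX). They also gave 10 (difference between lines), 11 (with CHX), 17 (lines in DMSO) and 5 (shared). The comparisons without CHX thus lost calls and the DEX+CHX comparisons gained them. Replicates correlated at 0.9876 to 0.9911 without CHX and at 0.9913 to 0.9937 with it. The shared spread may therefore be too small for the comparisons without CHX. Without the 3 arrays nearest to CHX, 42 rows differed in their DEX response and 9 between lines in DMSO.

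All rows of the table, which more than doubles the rows tested, gave 1017 and 1201 calls with DEX (PEAR1, PEAR2), 1127 and 2402 with DEX+CHX, 77 and 0 for the differences between lines without and with CHX, 22549 and 21912 for CHX with and without DEX, 63 for the lines in DMSO and 11 shared. With an estimated correlation 2 of the 4 list calls were left. The replicate block within each line gave 366 (PEAR1 DEX+CHX) and 9 (lines in DMSO). The numbers did not pair the samples, with correlations of -0.118 to 0.0642 between the deviations of equal numbers, so the block has no basis in the design.

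With an array left out the counts ranged over 349 to 455 (PEAR1 DEX), 465 to 646 (PEAR2 DEX), 227 to 574 (PEAR1 DEX+CHX), 696 to 980 (PEAR2 DEX+CHX), 5 to 56 (difference between lines), 0 to 9 (with CHX), 9277 to 9596 (CHX with DEX), 9181 to 9380 (CHX without DEX), 9 to 49 (lines in DMSO) and 1 to 4 (shared).

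MOL1 with CHX reversed to 0.0408 after quantile normalization once more. Set against DMSO of the same batch, DEX+CHX gave 8081 calls in the PEAR1 line and 7779 in the PEAR2 line. This control adds the effect of CHX, together with the difference between 1 h and 2 h. By the same construction these reversed in the PEAR1 line: AT1G73120 -0.32, AT2G28780 -2.11, AT4G00910 -2.73, AT3G51642 -0.71, AT5G17970 1.16, AT2G27320 2.49, AT2G03230 1.70, CCOAMT 1.95, AT4G09120 0.74, OPS -0.80, IAA30 2.79, AUR1 -0.59, MOL1 -0.51, CML38 5.73, GI -0.26, BBM 0.62, RCA -0.81. In the PEAR2 line these did: AT5G17040 -0.15, AT2G03230 1.89, AT2G44070 0.65, AT5G55270 0.0895, AT2G27320 2.45, AT4G09120 0.86, PHV -0.9995, OPS -0.76, SWEET11 -1.02, LHW -0.45, IAA29 3.17, IAA30 3.37, GH3.5 1.83, AUR1 -0.35, CLE44 2.01, CML38 5.97, GI -0.0744, EXPA18 -0.58, RCA -0.81.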

Other observations

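Families of genes that share a symbol stem were tested by a rule chosen after the data were seen. With CHX in the presence of DEX, all 7 named WRKY genes rose (camera adjusted p = 1.19e-05, adjusted p = 0.00936 with an estimated correlation), among them WRKY22 by 4.15 and WRKY6 by 1.53. All 7 genes of the calmodulin-like CML family rose (camera adjusted p = 1.58e-05, adjusted p = 0.00534 with an estimated correlation), with CML37 at 6.10 and CML23 at 4.41. Of 10 PUB genes, which encode U-box ubiquitin ligases, 8 rose (camera adjusted p = 1.16e-06, adjusted p = 0.00665 with an estimated correlation), PUB24 by 4.70. Of 9 BZIP genes 8 rose (camera adjusted p = 0.000447, adjusted p = 0.00868 with an estimated correlation), led by BZIP60 of the unfolded protein response at 3.89. The 7 genes under the stem ATBZIP did not move as a set: 2 rose and 2 fell (camera adjusted p = 0.807). Of 9 NRPB genes of RNA polymerase II, 8 fell (camera adjusted p = 0.0444, adjusted p = 0.104 with an estimated correlation), and 7 fell and 1 rose after quantile normalization once more.

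The beta-tubulin genes fell with CHX, and some stood higher with DEX+CHX than with DMSO+CHX. All 5 fell with CHX in the presence of DEX (camera adjusted p = 0.0227, adjusted p = 0.147 with an estimated correlation), and 2 of 5 rose with DEX+CHX in the PEAR1 line (TUB7 by 0.58 and TUB6 by 0.39, camera adjusted p = 0.00954, adjusted p = 0.253 with an estimated correlation). In the PEAR2 line 3 of 5 rose (TUB7 by 0.87, TUB1 by 0.72 and TUB6 by 0.67, camera adjusted p = 8.51e-05, adjusted p = 0.0350 with an estimated correlation). Beta-glucosidase genes fell as a set with DEX+CHX: 3 of 24 in the PEAR1 line (BGLU27, BGLU31 and BGLU32, camera adjusted p = 0.0176, adjusted p = 0.255 with an estimated correlation) and 5 of 24 in the PEAR2 line (BGLU16, BGLU24, BGLU27, BGLU31 and BGLU32, camera adjusted p = 0.0154, adjusted p = 0.161 with an estimated correlation). Of 16 genes under the stem TRM, which holds unrelated genes, 3 rose in the PEAR2 line (TRM27, TRM19 and TRM20, camera adjusted p = 0.0257, adjusted p = 0.128 with an estimated correlation). Most of these beta-tubulin and beta-glucosidase calls ran against the change with CHX in the presence of DEX. That change was -1.41 for TUB7, -0.92 for TUB1 and -0.82 for TUB6. It was 6.95 for BGLU27, 5.31 for BGLU31 and 2.59 for BGLU32, while BGLU16 (-0.10) and BGLU24 (-0.11) did not pass. The DEX+CHX comparisons are confounded with batch, so a CHX effect that differs in size between batches cannot be told apart from DEX.

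Named rows passed between the lines in each treatment: 15 higher and 18 lower in the PEAR1 line in DMSO, 36 and 92 in DEX, 3 and 17 in DMSO+CHX and 18 and 12 in DEX+CHX. The 200 rows most raised by CHX averaged 8.87 to 9.21 on the DEX+CHX arrays and 9.10 to 9.30 on the DMSO+CHX arrays. On the arrays without CHX they averaged 3.20 to 3.44, highest there in PEAR1 DMSO replicate 1 at 3.44.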
